A study of Bifidobacterium longum subsp. infantis ATCC 15697 = JCM 1222 = DSM 20088 and Bifidobacterium adolescentis
Bifidobacterium longum subsp. infantis ATCC 15697 = JCM 1222 = DSM 20088
Bifidobacterium bifidum PRL2010
Bifidobacterium breve 12L and Bifidobacterium longum subsp. infantis ATCC 15697 = JCM 1222 = DSM 20088
Bifidobacterium breve 12L with 5 samples.

How the data were processed

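Bifidobacterial RNA was measured on 10 Agilent 2-colour arrays, 2 for each of 5 samples. Every sample sets 1 RNA (the first-named RNA) against a reference RNA, and no group holds more than 1 sample. In the first sample, per the labels' protocols, B. longum subsp. infantis ATCC15697 (a bifidobacterium of the infant gut, here called ATCC15697) taken from mice was set against the same strain grown in a mouse food medium with 0.05% cysteine at 37 °C. In the other 4 samples, ATCC15697 given to mice with partners was set against ATCC15697 given to mice alone. The partners were B. breve 12L, B. bifidum PRL2010, B. adolescentis 22L, or all 3 together. Each group had 5 female BALB/c mice, 3 months old, which received 5 daily oral doses of 20 µl. The labels state 500 ng of total RNA and 5 µg of labelled cDNA, and they do not say how RNA of the 5 mice was combined.

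The deposited scanner files hold the intensity of each spot (mean of its pixels) and of its local background (median of the pixels), not normalized, per the file headers. They also hold Agilent's processed intensity, background-subtracted and dye-normalized, and a log10 ratio of Cy5 over Cy3 made from it, per the file headers. Flags of 0 or 1 for spots well above background, saturated or non-uniform are given in the same files, per the file headers. Features were extracted with Agilent Feature Extraction 11.5.1.1 per the file headers, while the submitters' processing notes name version 10.10, and limma. The deposited value table holds 1 signed value per ATCC15697 gene and sample. It was taken as a log2 ratio made by the authors, because its values followed the mean over probes and arrays of the scanner ratios with slopes of 0.969 to 0.99 (r of 0.97 to 0.99) in 4 samples. For the sample with B. adolescentis r was 0.457. Its medians were -0.01, 0.01, 0.07, 0.02 and 0.08 in the order mouse against food, all 4 strains, B. breve, B. bifidum and B. adolescentis. The scale and direction of that table are thus inferred from the values, and its centring stays unknown.

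Each array has 37603 features, with 36186 probes outside the controls and 153 negative controls. ATCC15697 has 11380 probes for 2400 genes, 2039 of them with 5 probes. Strains 12L, PRL2010 and 22L have 8697, 8130 and 7945 probes. The files name genes by locus tag only, and 0 of the 2400 tags were found among the 2665 genes of the annotation supplied, so products are not paired with tags here. Where a function is given beside a tag, it is background knowledge of this strain's genome. Of 22 gene lists fixed before the data were examined, 18 were defined by product names and were void for that reason. The other 4 were defined by locus tag: the human milk oligosaccharide cluster, the lacto-N-biose cluster, the N-acetylglucosamine cluster and the urease cluster. Another 2 lists (milk glycan hydrolases outside the large cluster, and family 1 solute-binding proteins) were added once the probe names were known and before any value was seen.

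The dyes were swapped between the 2 arrays of a sample. Across probes, the unturned ratios of the 2 arrays correlated at -0.319, -0.201, -0.712, -0.786 and -0.849, in the sample order given above. The labels put the first-named RNA in Cy5. Array II was taken to follow the labels and array I was turned. The sign of the deposited table goes with this choice, but its direction was itself inferred from these ratios and adds no support. This direction is likely: it rests on the labels and on which channels resemble each other across samples. In it, the reference channels of the samples with all 4 strains, B. breve and B. bifidum correlate with the mouse RNA of the first sample at a median Spearman's rho of 0.806 (0.689 to 0.886), with its food culture at 0.419 (0.363 to 0.477) and with each other between samples at 0.781 (0.693 to 0.863), against 0.615 (0.463 to 0.69) among the co-colonised RNAs. If array I followed the labels in these 4 samples, the food culture and not the mouse RNA would be the one like these channels, which the values argue against. The 2 food culture channels correlated with each other at only 0.411, so their 0.419 says little by itself. The argument rests on 0.806, and on 0.781 against 0.615. For the B. adolescentis sample, whose reference does not match, the direction is an assumption. The labels do not tell which array follows them, and array II was taken to do so. The design fixed before the data were examined gave Cy5 over Cy3 without a swap, which the arrays did not allow.

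Mean signals were corrected with limma 3.58.1 (R 4.3.3, with version 1.17.8 of its data.table package) by normexp with an offset of 50 on the local background, fitted on all spots. Ratios were then normalized within each array by loess (span 0.3, 4 iterations) in which only ATCC15697 probes had weight. Control and outlier spots were left out and saturated spots were kept. On array II of the B. adolescentis sample, 5557 spots (14.8%) had a signal of 0 and were left out. A gene's value per array is the median of its probes, and its value per sample is the mean of the 2 arrays, which were treated as 1 replicate. A gene without a value on both arrays has no value in that sample. This last requirement was set after values had been seen, when a gene with 1 probe and 1 usable array came out as the most extreme of the B. adolescentis sample.

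A gene counted as above background in a sample when a share of at least 0.5 of its probes was well above background, in the same RNA, on both arrays. It counted as measured on both sides when this held for both RNAs. Between 4.22% and 55.4% of ATCC15697 probes were well above background per channel, and the median signal of ATCC15697 probes was 59.0 to 1163 per channel, against 41.7 to 1110 for the negative controls. The number of arrays limits the precision. For a gene above background in 1 RNA and with no probe well above background in the other RNA on either array, only a bound is given, and none where it is under 1: the brighter RNA's mean against the higher of the dim probe's own level and the lowest level well above background, after loess and quantile scaling of the average intensity. A gene with some probes well above background in the other RNA, but a share under 0.5 of them, keeps its ratio, which rests on a dim side and is marked as above background in 1 RNA only.

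For each sample, genes with a log2 ratio of at least 1, or at most -1, on both arrays were counted, without a test. Values are given with the SD of the 2 arrays, which is technical. Over the 4 samples with partners, limma tested the mean ratio against 0 (the shared response) and each sample against the other 3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The first test leaves out the spread of the control RNA itself, and the second takes the lone sample to vary like the other 3. The 1302 genes tested were above background in at least 1 of the 4 samples. These p-values measure only the spread between these samples. Gene lists were tested by camera with a preset correlation of 0.01, again with an estimated one, and by fry, for lists with at least 4 tested genes. In single samples a list's median was ranked among 10000 random lists of the same size matched on intensity.

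Genes are named by a rule fixed before the data were examined. For single samples it takes the largest ratios of at least 1 in size among genes measured on both sides with the same sign on both arrays, the leading members of each list, and the largest bounds. For the tests it takes the leading genes per direction. For 1 sample against 3, genes outside the lists were afterwards limited to those measured on both sides, and Blon_1459, above background in 1 RNA only, is given among the settings because its sign turned. Because tags are not paired with products, at most 2 genes per direction and comparison are printed outside the lists. Blon_1722, the fructose-6-phosphate phosphoketolase, was to be named always, and luxS also, whose tag was not known and which is left out.

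The steps were tested on simulated data. With 200 of 1302 genes changed, the shared response test recovered 97% of genes changed by 1 and 100% of those changed by 2 on the log2 scale, and the test of 1 sample against 3 recovered 11% and 80%, with 8 and 3 false calls. These simulations had no control deviation shared by the samples, and with it the shared response test called a mean of 299 of 1302 unchanged genes (highest 368). The spot-level steps were run on 2400 genes of each sample's own arrays. In 200 genes, bright spots (95th percentile over the negative controls) were given a ratio of 2 on the log2 scale. The recovered ratio was 1.01 for mouse against food, 1.66 for all 4 strains, 1.70 with B. breve, 1.69 with B. bifidum and 1.95 with B. adolescentis. The simulation was redesigned after 2 earlier designs, which multiplied all signal over the local background, recovered too little of the change in mouse against food to pass. The values given therefore hold for bright spots only, and changes in dim spots were recovered less.

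Each slide held the 2 arrays of 1 sample (5 slides), so slide and sample cannot be told apart and the slide could not be used as a block. Alternatives fixed before the data were examined were: loess on all strains' probes, median centring without loess, Agilent's log ratio, no background correction, the mean of probes, no filter on dim genes, genes measured on both sides only, the deposited table, each array alone, a threshold of 1.5 on the log2 scale, limma with an intensity trend, and leaving out each sample. Alternatives added afterwards were: keeping the spots of 0, the negative controls as background, removing a trend with GC content, only probes with a value on both arrays, and, for the tests across samples, each array alone and, for each sample against the others, leaving out 1 of these. Shuffling the probes among genes (100 times) and simulating unchanged genes against 1 shared control (100 times, over 4 samples, and over 3 without B. adolescentis) were also added afterwards. In these simulations the control was given the same SD as the samples, which was assumed and not measured. Shuffled data had fewer genes above background than the data themselves, so their counts come from fewer genes.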

Results

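Gene expression of B. longum subsp. infantis ATCC15697 was measured in 5 samples, each 1 RNA set against another on 2 dye-swapped arrays. The first sample sets the strain taken from mice against its culture in mouse food. The other 4 set the strain given to mice with B. breve 12L, B. bifidum PRL2010, B. adolescentis 22L or all 3 of them against the strain given alone, and so ask how partners change its expression in the gut. Each comparison has n = 1 sample, so values carry the SD of the 2 arrays, which is technical, and no p-value. Of 2400 genes, 142 were above background for mouse against food, 159 with all 4 strains, 426 with B. breve, 336 with B. bifidum and 1231 with B. adolescentis. Positive log2 ratios mean a higher level in mice than in food, or with partners than alone. This direction is likely in 4 samples, from the labels and from which channels resemble each other. With B. adolescentis it was assumed, since the labels do not tell which of the swapped arrays follows them. Ratios of probes of 1 gene were hardly alike (intraclass correlation of 0.00529 to 0.0114 in the 5 samples), which the SD of the arrays does not show. Genes carry locus tags only in the files, and functions given beside them are background knowledge.

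Probes of the partner strains did not stand out in the samples that received those partners. With B. breve, the median log2 ratio of 12L probes exceeded that of ATCC15697 probes by 0.02 ± 0.02 (SD of 2 arrays). With B. bifidum, PRL2010 probes exceeded them by 0.01 ± 0.03, and with B. adolescentis 22L probes by 0.00 ± 0.00. At least 2-fold higher on both arrays were 7.82% of 12L probes with B. breve (7.48% of ATCC15697 probes), 3.35% of PRL2010 probes with B. bifidum (2.7%) and 4.77% of 22L probes with B. adolescentis (5.23%). In the RNA of the pure food culture, 4.22% of ATCC15697 probes and 3.96% of the other strains' probes were well above background on array I, and 15.3% and 15.0% on array II. PRL2010 probes were above background more often than ATCC15697 probes by a median of 5.04 percentage points over 20 channels, and by -1.13 points at matched GC content. For 12L and 22L probes the medians were -4.19 and -3.14 points, and -0.25 and -1.29 at matched GC content. There 22L probes stayed below ATCC15697 probes in every channel (highest -0.351), also where 22L was given. Probe signal thus did not tell the strains apart, which limits every value given for ATCC15697 genes.

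**Figure D1:**
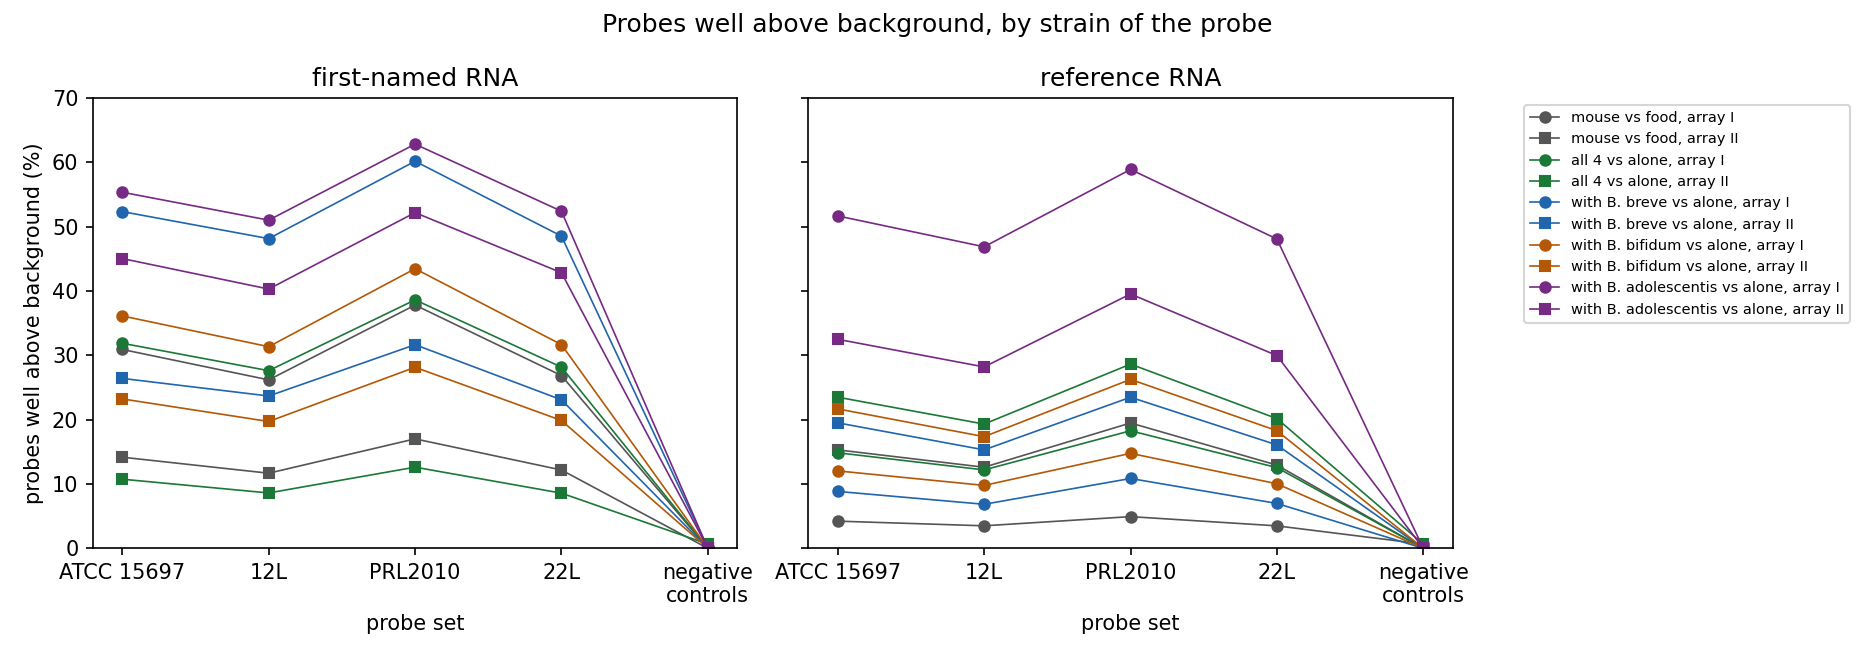
Share of probes well above background (%, vertical axis) by the strain a probe was designed on and for the negative controls (horizontal axis), with 1 line per channel, the first-named RNA on the left and the reference RNA on the right. Colours are the 5 samples, circles array I and squares array II. In every channel PRL2010 probes have the largest share and negative controls stay at or under 0.654%.

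For mouse against food, no gene differed by 2-fold on both arrays: 0 of the 142 genes above background were higher and 0 lower. Of these 142 genes, 133 were above background in the mouse RNA only, 3 in the food culture only and 6 in both. Most of the ratios thus rest on a dim side, and a count of 0 does not show an absence of change. Among genes above background in the mouse RNA only, Blon_1873 had the largest bound, at least 1.71-fold higher there, and Blon_0130 followed with at least 1.30-fold. None of the 28 genes of the milk oligosaccharide cluster was above background in either RNA, and the cluster's median log2 ratio was 0.00. For the lacto-N-biose, N-acetylglucosamine and urease clusters, medians were 0.02, 0.03 and 0.01, again with 0 genes above background. Ratios of the 2 arrays correlated across genes at r = 0.0813 (genes are not independent replicates), and a simulated log2 ratio of 2 in bright spots was recovered as 1.01. With median centring in place of loess, 33 genes were higher and 0 lower, but in that setting 100 of 200 simulated genes had the right sign. Agilent's log ratio gave 44 higher and 3 lower.

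With all 4 strains, 2 genes were higher and 2 lower by at least 2-fold on both arrays, of 159 above background. None of these 4 was measured in both RNAs. By the mean of the arrays, and not by 2-fold on each, the largest ratios among genes measured in both were 1.27 ± 0.42 for Blon_1676, 1.18 ± 1.11 for Blon_1136, -1.44 ± 1.05 for Blon_1459 and -1.11 ± 0.77 for Blon_1402 (log2, SD of 2 arrays). In the milk oligosaccharide cluster, Blon_2356 was at 0.46 ± 0.44, above background with the partners only. When probes were shuffled among genes, a median of 2 genes were higher and 5 lower, and at least 2 were higher in 52 of 100 shuffles, which had a median of 96 genes above background. Ratios of the 2 arrays correlated at r = 0.0245 across genes, and median centring gave 9 higher and 3 lower, Agilent's log ratio 4 and 11, and array I alone 5 and 20.

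With B. breve, 20 genes were higher and 6 lower by at least 2-fold on both arrays, of 426 above background, and 1 and 2 among genes measured in both RNAs. Of the latter, Blon_2255 had a log2 ratio of 1.35 ± 0.01, with its 2 probes at 0.34 and 2.37, and Blon_1873 of -2.10 ± 0.32, with both of its probes below 0, and Blon_2010 was at -1.19 ± 0.39 by the mean of the arrays, not 2-fold on each. With no probe well above background in the reference RNA there were 46 genes, 20 of them with a bound above 1 and Blon_2214 with the largest, at least 4.68-fold higher. Of the milk oligosaccharide cluster, 4 of 28 genes were above background, with the partner only, of which Blon_2343 was at least 1.5-fold higher, Blon_2353 and Blon_2356 were at -0.43 and -0.11, and Blon_2338 had no bound above 1. At least 20 genes were higher in 7 of 100 shuffles of probes among genes (median 14), and at least 6 lower in 41 (median 5), with a median of 345.5 genes above background in the shuffles. Agilent's log ratio gave 70 higher and 5 lower, array I alone 44 and 20, and no background correction 5 and 3. Median centring gave 100 higher and 1 lower and turned Blon_2010 to 0.46.

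With B. bifidum, 6 genes were higher and 2 lower by at least 2-fold on both arrays, of 336 above background, and 1 and 1 among genes measured in both RNAs. Blon_1669 had a log2 ratio of 1.35 ± 0.40, and Blon_0073, above background with the partner only, was at least 2.02-fold higher. Blon_1873 was at -1.25 ± 0.16, with 1 of its 2 probes below 0, and Blon_0152 at -1.39 ± 0.69 by the mean of the arrays, not 2-fold on each. In the milk oligosaccharide cluster, 1 gene was above background, Blon_2356 at -0.20 ± 0.27, with the partner only. At least 6 genes were higher in 4 of 100 shuffles of probes among genes (median 2), and at least 2 lower in 67, with a median of 260.5 genes above background in the shuffles. Median centring gave 9 higher and 0 lower, Agilent's log ratio 42 and 19, array I alone 46 and 25, and the negative controls as background 20 and 14.

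With B. adolescentis, 20 genes were higher and 44 lower by at least 2-fold on both arrays, of 1231 above background, and 6 and 35 among genes measured in both RNAs. Blon_0071 had a log2 ratio of 2.34 ± 0.61 and Blon_1831 of 1.56 ± 0.10. Blon_0533 was the lowest at -3.31 ± 0.08, with its 2 probes at -5.46 and -1.16, followed by Blon_0265 at -3.16 ± 0.49. In the milk oligosaccharide cluster 9 of 28 genes were above background, 2 of them in both RNAs, in the lacto-N-biose cluster 2 of 7 and 0, in the N-acetylglucosamine cluster 6 of 8 and 1, and in the urease cluster 4 of 12 and 0. Among genes above background, the largest ratios of the 4 clusters were 0.82 ± 0.10 for Blon_2348 (a sialidase), 0.37 ± 0.40 for Blon_2173 (nahK, N-acetylhexosamine kinase), 2.24 ± 1.04 for Blon_0879 and 2.04 ± 0.66 for Blon_0115. All 4 genes were above background with the partner only, so these ratios rest on a reference near background. Bounds could be given for 9 higher genes, the largest at least 2.76-fold, and for 2 lower genes, the larger at least 2.33-fold. At least 20 genes were higher in 1 of 100 shuffles of probes among genes (median 12), and at least 44 lower in 0 (median 26, highest 40), with a median of 1208 genes above background in the shuffles. The reference RNA of this sample did not match that of the other samples (median Spearman's rho of 0.598 across probes, against 0.781 among the others), median centring gave 89 higher and 6 lower and Agilent's log ratio 135 and 103, and the deposited value of Blon_0265 was 0.47.

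Most genes of the clusters were not above background, so their medians say little about the clusters. Of 20 medians (4 clusters in 5 samples), the largest in size was 0.33, and 2 lay outside the middle 95% of random lists, where 1 was to be expected by chance. That count was 8 with Agilent's log ratio and 0 with median centring. The N-acetylglucosamine cluster (8 genes) with B. breve had a median log2 ratio of 0.33, at percentile 98.0. The lacto-N-biose cluster (7 genes) with all 4 strains had -0.23, at percentile 2.07. The milk oligosaccharide cluster ranged from percentile 11.1 with B. breve to 82.9 with B. adolescentis, and the urease cluster (12 genes) from 21.5 with B. breve to 80.2 with B. adolescentis. Blon_1722, the fructose-6-phosphate phosphoketolase of the central fermentation pathway, was not well above background in any sample, with log2 ratios from -0.12 with B. bifidum to 0.28 with B. breve.

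**Figure D2:**
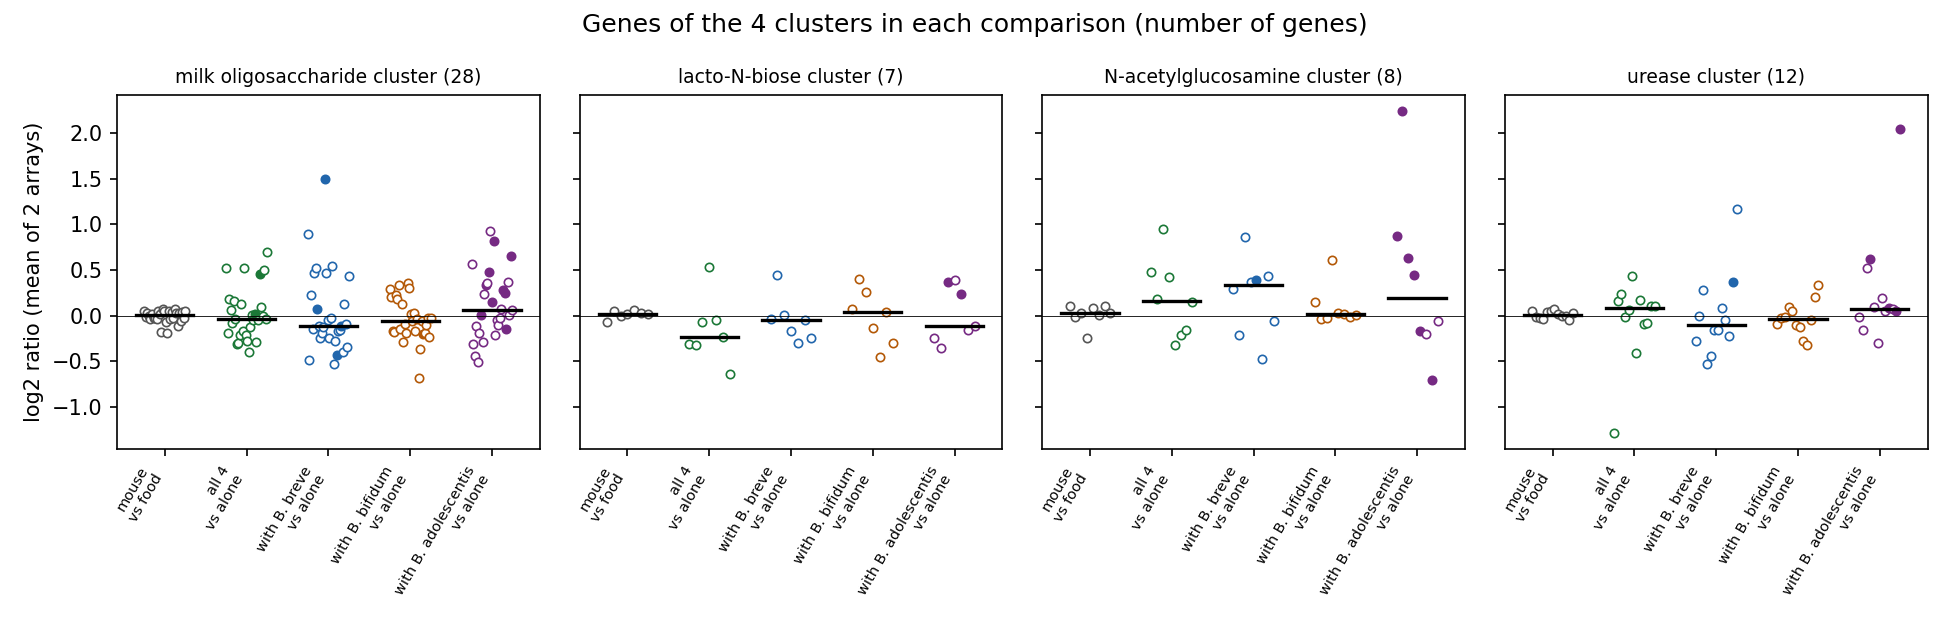
Log2 ratio (vertical axis, mean of 2 arrays) of each gene of the 4 clusters in the 5 comparisons (horizontal axis). Filled points are genes above background, open points genes that were not, and black bars medians of all genes of the cluster. Most points are open, and no median exceeds 0.33 in size.

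By limma, 0 of 1302 genes were called for a response shared by the 4 samples with partners, with a smallest adjusted p of 0.14. The count depended on the setting, with 76 genes higher and 86 lower in the deposited table, 8 and 4 with array I alone, and 0 and 5 with the mean of probes. The deposited B. adolescentis values went with the other samples' reference channels (r of 0.803), so all 4 samples of that table may share 1 control. Unchanged genes simulated against such a control, with an assumed SD, gave a mean of 299 calls of 1302 genes. The calls in the deposited table thus cannot be taken as a response, nor put down to the control. In the main setting, 147 genes were at an unadjusted limma p under 0.05, against 65.1 by chance. Shuffling probes among genes gave a median of 133.5 (147 or more in 13 of 100 shuffles). Unchanged genes simulated against 1 control shared by all 4 samples gave a mean of 476. The mismatched reference RNA of the B. adolescentis sample leaves such sharing in doubt. Blon_1873 led at -1.47 ± 0.25 (SE, limma, adjusted p = 0.14, below 0 in 4 of 4 samples), and among positive values Blon_1565 at 0.74 ± 0.16 (adjusted p = 0.159, above 0 in 4 of 4). The N-acetylglucosamine cluster had 6 tested genes with a median of 0.45 and passed camera (adjusted p = 0.0405), but had adjusted p = 0.255 with an estimated correlation and 0.0543 by fry. Of its genes, 0 were above background with all 4 strains, 1 with B. breve, 0 with B. bifidum and 6 with B. adolescentis. Values of the first 3 samples were therefore mostly dim. With median centring, Agilent's log ratio, no background correction, the GC trend removed or no filter on dim genes, 0 clusters passed camera. The N-acetylglucosamine cluster's count of called genes was 0 over all genes and 2 adjusted over the list alone. The milk oligosaccharide cluster (9 tested genes, median 0.05) had a camera adjusted p of 0.724 and 0 called genes, also adjusted over the list alone. The urease cluster (4 tested genes, median 0.11) had 0.327, with 0 called over all genes and 1 adjusted over the list alone. Without the B. adolescentis sample, 13 of 578 genes were called lower and 0 higher, among them Blon_1873 at -1.79 (limma, adjusted p = 0.00681). These 3 samples share 1 control per the labels. Simulations of 578 unchanged genes against such a control gave 88.8 calls on average and at least 13 in 99 of 100. There the control deviated by the same SD as the samples, a size that was assumed. Since the real deviation was not measured, the 13 calls cannot be taken as a response, nor put down to the control.

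By limma, 41 genes were higher and 64 lower with B. adolescentis than in the other 3 samples, of 1302 tested. This sets 1 sample, which has no spread of its own and is taken to vary like the others, against 3. That is in doubt: its ratios had an SD over tested genes of 0.609, against 0.338 to 0.511 in the others. It had 592 genes measured on both sides, against 35 to 64, and 578 genes would be tested without it. Its reference RNA did not match theirs (rho of 0.598 against 0.781), so the calls cannot be assigned to the partner. The other samples' tests hold it among their 3. Such a test recovered 11% of simulated genes changed by 1 on the log2 scale, so few calls do not show likeness. Of the called genes above background in both RNAs, Blon_0071 had the largest positive difference, 2.03 ± 0.37 on the log2 scale (SE). In 5 of 14 alternative settings its call was lost, with differences of 1.9 to 2.63 there. Blon_0265 differed by -3.24 ± 0.37 (adjusted p = 1.62e-06) and Blon_0533 by -3.10 ± 0.37 (adjusted p = 2.34e-06). With the deposited table the differences were 0.31 for Blon_0265 and -1.14 for Blon_0533, and with median centring -2.52 and -2.55. Both settings ended the calls of both genes. In the N-acetylglucosamine cluster 1 of 6 tested genes was called, Blon_0879, by 2.27 ± 0.37 (adjusted p = 0.000219), and in the urease cluster 1 of 4, Blon_0115, by 1.51 ± 0.40 (adjusted p = 0.016), with the same counts adjusted over the list alone. Both genes were not above background in the reference RNA, and of 14 alternative settings 3 ended the call of Blon_0879 and 8 that of Blon_0115. In the milk oligosaccharide cluster 0 of 9 were called. Of the 105 genes, 48 were above background in no other of the 4 samples. At least 105 genes were called in 5 of 100 shuffles of probes among genes (median 53.5, highest 124), and the call count was 8 (7 higher, 1 lower) with median centring and 2 with the deposited values. For the sample with all 4 strains limma called 0 genes (30 at an unadjusted p under 0.05), with B. breve 0 (52) and with B. bifidum 0 (10), where 65.1 were to be expected by chance.

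**Figure D3:**
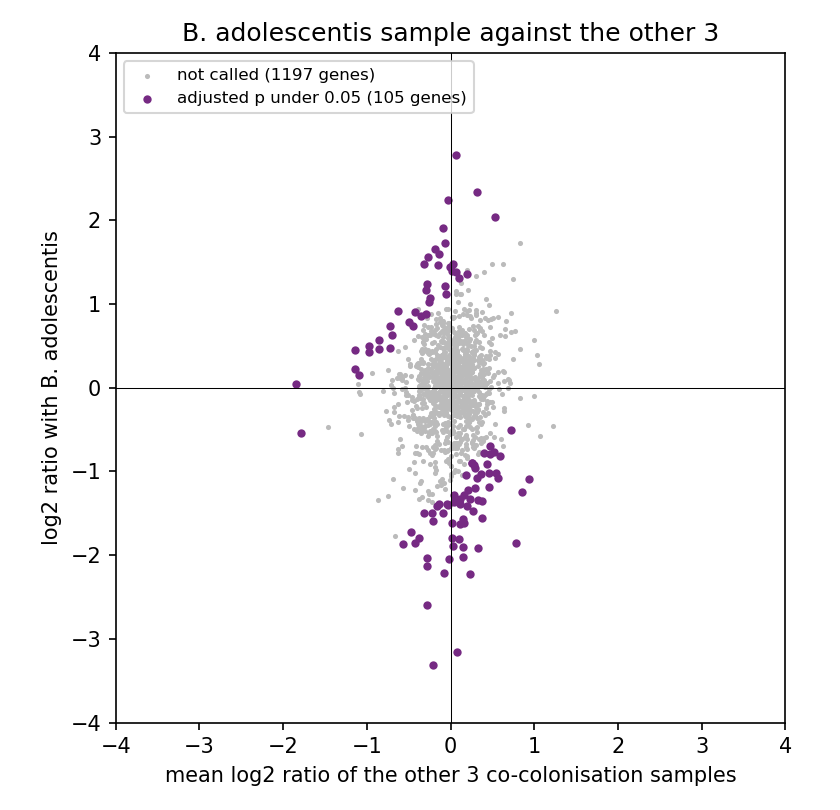
Log2 ratio with B. adolescentis (vertical axis) against the mean log2 ratio of the other 3 samples with partners (horizontal axis), with 1 point per tested gene. Purple points are the 105 genes with a limma adjusted p under 0.05 for the difference. Tested genes spread from -3.31 to 2.78 on the vertical axis.

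Ratios of the other 3 samples with partners resembled each other across 1302 genes, which are not independent replicates. Most of these genes entered through the B. adolescentis sample, since 578 genes would be tested without it. In the other 3 samples most of these ratios are thus of genes not above background. Pearson's r was 0.316 between all 4 strains and B. breve, 0.292 between all 4 strains and B. bifidum, and 0.403 between B. breve and B. bifidum (Spearman's rho 0.279, 0.231 and 0.339). With B. adolescentis r was 0.0325, 0.0685 and 0.0586. Among the 16 genes measured on both sides in all 4 samples, the mean r between samples was -0.0577, against 0.195 over the 1302 genes. Unchanged samples simulated against 1 shared control gave a mean r of 0.501 and a mean covariance of 0.153. Observed covariances between the first 3 were 0.0659, 0.0403 and 0.0697. The simulation gave the control the same SD as the samples, which itself sets r near 0.501. It was also set for all 4 samples, of which B. adolescentis spread most (SD of 0.609, against 0.338 to 0.511). A shared control can make unchanged samples alike, but its own deviation was not measured. In mouse against food, RNA of ATCC15697 given alone is the first-named RNA, so a deviation of the same RNA would turn its sign there. Pearson's r with mouse against food was -0.198 for all 4 strains, -0.156 for B. breve, -0.19 for B. bifidum and 0.0126 for B. adolescentis. The 3 negative values go with a part of the control. Whether that RNA was the same was not tested, and most of these ratios rest on a dim side. The size of the control's part in the observed similarity therefore cannot be told.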

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

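The tests of array quality and of RNA from the gut or the host, and the test of identical sequences, were chosen after the results were seen. The tests of GC content and signal, of likeness of probes by gene, and of the deposited values were fixed before the values they measure were seen.

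Probes of the 3 strains that were not given stood well above background in the sample of mouse against food, in data that the comparisons do not use, with shares of 30.2% (mouse RNA, array I), 3.96% (food culture, array I), 15.0% (food culture, array II) and 13.6% (mouse RNA, array II), against 0% to 0.654% of the negative controls. RNA of gut microbes or of the host as the whole of this signal is argued against by the food culture, which holds no gut contents: there the share of ATCC15697 probes exceeded that of the other strains' probes by at most 0.34 percentage points. Wrongly assigned probe names predict probes of 1 gene to be no more alike than others, and the intraclass correlation after removing the GC trend was indeed 0.0131, as that explanation needs. Signals of spots listed with the identical sequence correlated at a median of 0.94, which argues only against sequences listed for the wrong spots. GC content of the listed sequences was alike within a gene (intraclass correlation of 0.569), which argues against sequences scattered at random among genes. Whether the sequences belong to the genes named was not tested further, so names exchanged between whole genes stay open. GC content stays open as a candidate explanation of probe brightness, with a median Spearman's rho of 0.457 with signal across ATCC15697 probes, and no biological explanation was tested.

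In the sample with B. adolescentis, 105 genes differed from the other 3 samples with partners by limma (adjusted p under 0.05), a test that takes this lone sample to vary like the other 3. Shuffling the probes among genes gave a median of 53.5 genes and at least 105 in 5 of 100 shuffles. The reference RNA of this sample did not match that of the others: its channels correlated with theirs at a median Spearman's rho of 0.598, while theirs correlated with each other between samples at 0.781. It correlated with the mouse RNA of the first sample (ATCC15697 alone) at 0.638 and with the co-colonised RNA of the other samples at 0.639. With its own co-colonised RNA rho was 0.699, and with the food culture 0.434. Its arrays had 244 and 125 outlier probes, against 16 to 77 on the others. A strip of 5557 spots on array II had a signal of 0. All of these were left out. Its 2 reference channels correlated with each other better than with the others' by 0.319, which argues against noise of a single array as the cause. A fault shared by the slide would pass this test, since both arrays lay on 1 slide. The 2 channels were also brighter, with 51.7% and 32.5% of ATCC15697 probes well above background. In the reference channels of the other samples with partners the share was 8.84% to 23.5%. Its ratios also spread more over tested genes (SD of 0.609, against 0.338 to 0.511 in the other 3), which puts the test's assumption in doubt. A fault of the slide, another reference RNA, a wrong label and an effect of B. adolescentis itself stay open, since 1 sample on 1 slide holds them all.

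The deposited values of the B. adolescentis sample followed the other samples more than its scanner files did: their correlation with the deposited values of the other 3 samples was 0.439 to 0.53, against 0.0296 to 0.0585 for the probe means. When the reference channels of the other samples replaced its own, the correlation with the deposited values rose by 0.346, from 0.457 to 0.803. This is consistent with the authors having set its test channels against the control channels of the other samples, which nothing in the labels states. Correlations are across genes, which are not independent replicates, and no biological explanation was tested.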

How the results depend on the processing

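The settings that kept spots of 0, took negative controls as background, removed a GC trend, used only probes with a value on both arrays, used each array alone in the tests across samples, or left out 1 of the other samples in the difference of each sample were chosen after seeing the data. In the main setting the counts of genes higher and lower by at least 2-fold were 0 and 0 for mouse against food, 2 and 2 with all 4 strains, 20 and 6 with B. breve, 6 and 2 with B. bifidum, and 20 and 44 with B. adolescentis. The B. adolescentis difference had 105 genes, the shared response 0, the clusters passing camera were 1 of 3, and 2 of 20 cluster medians lay outside random lists. Counts that moved by over 1.5 times follow, and the cause was not tested except where fewer genes (genes measured on both sides) or a stricter threshold give it. Signal over background limits all of them: 6, 35, 45, 64 and 592 genes were measured on both sides, in the same order.

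With median centring, 33 genes were higher for mouse against food, 9 with all 4 strains, 100 with B. breve (1 lower) and 89 with B. adolescentis (6 lower), 0 were lower with B. bifidum, 8 genes were in the B. adolescentis difference, 0 cluster medians and 0 clusters passed, the partner probes' excess was -0.0119 (0.0121 in the main setting), and Blon_2010 with B. breve turned to 0.46. With Agilent's log ratio, counts were 44 and 3 for mouse against food, 4 and 11 with all 4 strains, 70 higher with B. breve, 42 and 19 with B. bifidum, and 135 and 103 with B. adolescentis, with 66 genes in its difference, 8 cluster medians and 0 clusters. Without background correction they were 1 and 1 with all 4 strains, 5 and 3 with B. breve, 9 lower with B. bifidum and 39 higher with B. adolescentis, with 337 in its difference, 1 cluster median and 0 clusters. With the negative controls as background, 3 genes were lower for mouse against food, 20 higher and 14 lower with B. bifidum and 55 higher with B. adolescentis, with 211 in its difference. With spots of 0 kept, 8 genes were higher with B. adolescentis. With the GC trend removed, 3 were lower with B. breve and 1 with B. bifidum, with 1 cluster median and 0 clusters. With probes on both arrays only, 1 cluster median lay outside, and with loess on all strains 0.

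With the mean of probes, 4 genes were lower for mouse against food, 7 with all 4 strains and 12 with B. breve, 14 higher and 6 lower with B. bifidum, and 33 and 71 with B. adolescentis, with 203 in its difference, 5 lower in the shared response and 1 cluster median. Without a filter on dim genes, 9 were lower with all 4 strains and 13 with B. breve, and 0 clusters passed. Among genes measured on both sides, 0 and 0 remained with all 4 strains, 1 and 2 with B. breve, 1 and 1 with B. bifidum and 6 higher with B. adolescentis, with 2 of 16 in its difference and a mean correlation between samples of -0.0577 (0.195 in the main setting). With the deposited table, counts were 1 and 7 for mouse against food, 8 and 12 with all 4 strains, 57 and 14 with B. breve, 25 and 15 with B. bifidum and 88 higher with B. adolescentis, 2 in its difference, 76 higher and 86 lower in the shared response, and a mean correlation of 0.475. Its log2 ratio of Blon_0265 with B. adolescentis was 0.47, and the differences of Blon_1459 and Blon_0265 turned to -0.63 and 0.31 (1.89 and -3.24 in the main setting). With array I alone, 3 were lower for mouse against food, and counts were 5 and 20, 44 and 20, 46 and 25, and 124 and 113 in the samples with partners, in the order given, with 8 higher and 4 lower in the shared response and 0 cluster medians. With array II alone, they were 4 and 1 for mouse against food, 20 and 15 with all 4 strains, 45 and 17 with B. breve and 35 and 75 with B. adolescentis, with 23 in its difference and 0 cluster medians. At a log2 threshold of 1.5, 0 and 1, 5 and 1, 0 and 0, and 8 and 13 genes were left in the samples with partners. With camera's estimated correlation 0 clusters passed, and by fry 0.

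Leaving out each sample in turn gave 0 to 13 genes lower in the shared response (13 without B. adolescentis), 0 to 2 in the B. breve difference (2 without B. bifidum) and 80 to 98 in the B. adolescentis difference. The differences of the samples with all 4 strains and with B. bifidum stayed at 0 genes by limma in all 18 settings each. Of 155 values of named genes in the B. adolescentis difference, 120 kept direction and call, 33 lost the call and 2 turned. Blon_0533 and Blon_0265 lost it with median centring (adjusted p = 0.0549 and 0.0691), and Blon_0533 with the deposited table and Agilent's log ratio (adjusted p = 0.387 and 0.0704). Of 276 values of named genes in single comparisons, 208 stayed within the SD of the arrays, 66 moved and 2 turned, and of 240 cluster medians 156 stayed and 84 moved. Of 72 values in the shared response, 64 kept their side of the threshold and 8 passed it. Quantile scaling of average intensities was not run as an alternative, since it leaves the ratios within an array unchanged, nor was the slide as a block, since each slide holds 1 sample. No paired analysis was possible because each group holds 1 sample.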

Other observations

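Of the 2 lists added once the probe names were known, milk glycan hydrolases outside the large cluster (7 genes) had medians at percentiles 29.1 for mouse against food, 95.5 with all 4 strains, 78.6 with B. breve, 67.9 with B. bifidum and 13.9 with B. adolescentis. Family 1 solute-binding proteins (11 genes, which take up oligosaccharides) were at 98.8, 8.66, 15.8, 57.4 and 46.5 in the same order. In the first of these the median log2 ratio was 0.04, and 0 of the 11 genes were above background. Of these lists, 2 and 1 genes entered the tests across samples, and limma called 0 of them, with Blon_0248 of the hydrolases nearest in the B. adolescentis sample at -0.75 ± 0.37 (SE, difference from the other 3, adjusted p = 0.237).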
